A study of Mus musculus with 7 samples.

How the data were processed

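Control and induced C3H10T1/2 cultures were profiled by RNA sequencing in 7 libraries. Per the labels, total RNA was extracted with Trizol and libraries were made from fragmented mRNA with a TruSeq v2 kit, which does not mark strand. The dose of dexamethasone is left out here because the labels write it ambiguously. The submitters' processing notes name Trimmomatic, HISAT2, featureCounts and the mm10 build, and the versions of the trimmer and aligner are not given in the sources used here. Per the file headers, the deposited counts are whole fragment counts per gene from featureCounts 1.6.4, summed over exons of the Ensembl 94 annotation, without strand, multi-mapping or overlap options, and they are not normalised. Sense and antisense reads were therefore counted alike, and fragments that overlap several genes or align to several places were not counted. The deposited exon length in bases, also per the file headers, was used for checks of length only.

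The table names its columns by number. They were matched to samples through the counting command on the table's own header line, whose input names equal the submitters' sample descriptions, taken in the order that featureCounts writes its columns. All 7 columns of values were matched in this way, and this mapping could not be checked independently. Of 54532 features 54409 had a symbol in the gene name table used here, and the 123 without one held at most 0.061% of the counts of a library. A total of 24769 features had 0 counts in every library. Chi-square values per degree of freedom between libraries of 1 group were 13.56 to 148.17, far above sampling noise. The lowest was that of OB 3 and OB 4, whose log2 CPM correlated at r = 0.99. These values do not show that the cultures were independent. The submitters' descriptions of OB 3 and OB 4 differ only in 1 digit, whose meaning the labels do not give. Each library was counted as 1 replicate because the design text calls the replicates biological, and p-values measure the spread between these libraries.

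Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept with filterByExpr, libraries were scaled with TMM factors (0.981 to 1.024), and OB was compared with control by the quasi-likelihood test with Benjamini-Hochberg adjustment over 15441 genes at a threshold of 0.05. The common biological coefficient of variation was 26.9%. The SE of a log2 fold change is its absolute value divided by the square root of the quasi-likelihood F statistic. Log2 CPM used a prior count of 2. Gene lists with at least 5 tested members were tested with camera from limma 3.58.1 at its preset correlation of 0.01, again with an estimated correlation, and with fry, each adjusted over 23 lists. Pooled levels of rare genes have 95% exact Poisson intervals, and ratios with 1 to 3 counts in control have exact binomial intervals, which cover counting error only. Total counts were 21213328 to 46530017 per library, so that 3 counts equal 0.0645 to 0.141 CPM.

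The design, the 25 lists, the alternatives and the rule for named genes were fixed before the data were examined. Named were the 10 largest log2 fold changes in each direction among genes past the threshold, with a mean log2 CPM of at least 2 and no overlap between the libraries of the groups, leaving out predicted and clone names. Named in any case were Runx2, Sp7, Alpl, Bglap, Ibsp, Spp1, Col1a1, Dlx5, Pparg, Fabp4, Sox9, Acan, Acta2, Fkbp5, Tsc22d3, Zbtb16, Mki67 and Vegfa. Of each list up to 4 called members were named in order of p, with the 2 of highest expression added where fewer than 2 passed. Genes that met this rule but are left out of the text are not reported here. The lists covered osteoblast, adipocyte, chondrocyte, smooth and skeletal muscle, stromal, macrophage, endothelial and epithelial markers, glucocorticoid receptor targets, collagen modification, matrix, mineralisation, cell cycle, interferon, inflammation, BMP and TGF-beta, Wnt, Notch, hypoxia, cholesterol synthesis, amino acid and unfolded protein stress, NRF2 targets, immediate early genes and oxidative phosphorylation.

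Replicate numbers in the labels met a rule fixed in advance for pairs, that the deviations from the group means correlate above 0.1 in every pair. The correlations across genes were 0.17, 0.52 and 0.40 for numbers 1, 2 and 3, although OB 1 correlated more with control 2 (0.21). Control 3 also correlated above this bound with OB 4 (0.27), which has no control of its number. The numbers follow the label sets, so the rule cannot tell true pairs from a shared label set. The counts of calls under the block had been seen before these correlations were computed. OB 4 is alone in its block and adds nothing to the blocked comparison. The blocked values are given beside the results they change.

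Alternatives were DESeq2 size factors in edgeR, upper-quartile scaling, no filter on low counts, DESeq2 1.42.0, limma-voom with quality weights, a block on replicate number, a block on the label set, a threshold of 0.01, glmTreat against a fold change of 1.5, each label set alone and each library left out in turn. Overlap with other genes was measured as shared exon bases and as shared 50-base words of transcripts. The tests were checked on simulated counts of 15441 genes for 4 OB against 3 control libraries, with 200 genes changed. There edgeR recovered 0% of genes changed by 1.5-fold, 40.3% of those changed by 2-fold and 80.3% of those changed by 4-fold, with 7 false calls (8.0% of calls). DESeq2 recovered 22.4%, 76.1% and 90.9% with 53 false calls (29.6%), and limma-voom 0%, 38.8% and 80.3% with 4 false calls (4.8%). The simulated counts were drawn gene by gene from edgeR dispersions, without an offset between label sets. Fewer genes were changed than were called in the real data, so these shares need not hold there.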

Results

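Messenger RNA was sequenced from C3H10T1/2 cells, a mouse mesenchymal line that can be driven towards bone, fat, cartilage and muscle fates in culture. The control group had 3 libraries of untreated cells. The OB group had 4 libraries of cells kept for 3 days in medium with 50 µM ascorbic acid, 10 mM β-glycerophosphate and dexamethasone, a synthetic glucocorticoid. The design text calls the replicates of both groups biological. Total counts on genes were 46530017, 35391045 and 25689889 in control 1, 2 and 3, and 24816216, 43403730, 21213328 and 23618141 in OB 1, 2, 3 and 4. Levels are given as CPM, the count relative to the scaled library total, and a count of 3 equals 0.0645 to 0.141 CPM in a single library. The columns of the deposited table carry no condition in their names. Every group assignment rests on the order of inputs in the counting command that the table records. The libraries also fell into label sets, because the submitters' descriptions start with C1 for control 1 and OB 1, with C2 for control 2 and OB 2, and with no C number for control 3, OB 3 and OB 4. The first principal component of log2 CPM held 53.1% of the variance and placed control 3 at -96.9, control 1 and 2 at -23.0 and -25.3, and the OB libraries between 20.0 and 52.0. The second component held 23.2% and placed OB 3, OB 4 and control 3 at -40.7, -32.1 and -27.1, and the other libraries between -0.3 and 50.0.

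The comparison of OB with control asked which genes change early in osteoblast induction. Zbtb16, a zinc finger transcription factor gene, rose from 1 count over the 3 control libraries to 12120 counts over the 4 OB libraries, and Hif3a, which encodes a hypoxia-inducible factor subunit, rose from 1 to 4115 counts. The ratio of pooled CPM was 11500 for Zbtb16 (95% exact binomial interval 2070 to 455000) and 3910 for Hif3a (702 to 155000). These intervals, like all others on counts here, cover counting error only. A pair of aldehyde dehydrogenase genes rose as well, Aldh1a1 from 0.648 ± 0.144 CPM (SD, n = 3) to 136 ± 29.6 CPM (SD, n = 4) and Aldh1a7 from 1.04 ± 0.145 to 271 ± 97.3 CPM. Ism1, which encodes a secreted protein, rose from 0.0871 ± 0.0311 to 13.2 ± 3.20 CPM. Among genes that fell, Lrrtm2, a synaptic adhesion gene, went from 8.50 ± 3.24 to 0.884 ± 0.227 CPM. Cdc25c, a phosphatase gene that drives entry into mitosis, fell from 29.5 ± 12.0 to 5.39 ± 0.509 CPM. Sapcd2 fell from 19.3 ± 9.86 to 2.81 ± 0.923 CPM, and Col8a1, a short-chain collagen gene, from 8.91 ± 5.48 to 0.746 ± 0.468 CPM. By edgeR the log2 fold changes of Zbtb16 and Hif3a were 12.93 ± 0.37 (SE) and 11.41 ± 1.24, with adjusted p = 8.2e-06 and 0.00496. Those of Aldh1a1, Aldh1a7 and Ism1 were 7.71 ± 0.28, 8.01 ± 0.40 and 7.22 ± 0.37, with edgeR adjusted p = 2.82e-05, 0.00017 and 0.00017. For Lrrtm2, Cdc25c, Sapcd2 and Col8a1 they were -3.27 ± 0.33, -2.45 ± 0.29, -2.79 ± 0.43 and -3.60 ± 0.60, with edgeR adjusted p = 0.00383, 0.00613, 0.0127 and 0.0157. The calls of these 9 genes held whichever library was left out. Each SE of a log2 fold change was derived from the F statistic of the test. For Zbtb16 and Hif3a, with 1 control count each, the SE does not cover the counting error shown by the intervals above. Counts were taken over exons, and Zbtb16 (ENSMUSG00000066687) lies at 48654297 to 48836222 on chromosome 9 of mm10, Hif3a (ENSMUSG00000004328) at 17031507 to 17062427 on chromosome 7 and Aldh1a1 (ENSMUSG00000053279) at 20492715 to 20643462 on chromosome 19.

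Further large rises were those of Lcn2, Timp4, Slc10a6 and Ctla2a, with log2 fold changes of 9.13, 7.52, 7.22 and 7.21 (edgeR adjusted p = 0.0281, 0.0335, 0.00599 and 0.00613). The rest of the 10 largest falls were Prl2c3, Ak4, Il1rl1, Akap6, Arhgap22 and Itgb7, with log2 fold changes of -3.92, -3.43, -2.97, -2.59, -2.55 and -2.47 (edgeR adjusted p = 0.0461, 0.0337, 0.0455, 0.0221, 0.0297 and 0.0228). Several were uneven within a group. Timp4, which encodes an inhibitor of metalloproteinases, stood at 10.2, 37.5, 1.16 and 1.70 CPM in OB 1 to 4. Lcn2 stood at 5.86, 21.3, 0.649 and 1.45 CPM in the same libraries. Control 3 stood apart from control 1 and 2 for Il1rl1, an interleukin receptor gene, at 130 against 18.9 and 14.8 CPM. It also did for Ak4 at 46.7 against 7.28 and 5.78 CPM, and for Prl2c3 at 24.1 against 1.43 and 2.68 CPM. Slc10a6 and Ctla2a kept their calls without each library in turn. The calls of Lcn2 and Timp4 ended without control 1, 2 or 3 or OB 1 (adjusted p up to 0.101 and 0.108), and that of Timp4 also by limma-voom (0.0801). The calls of Ak4, Il1rl1 and Arhgap22 ended without any of OB 1 to 4 (up to 0.108, 0.123 and 0.0836), and that of Prl2c3 without those or control 2 (up to 0.131). Without control 2, OB 1 or OB 2 the calls of Akap6 and Itgb7 ended (up to 0.0763 and 0.0772), as did that of Akap6 without OB 3 and that of Itgb7 without OB 4. Under the replicate block Prl2c3, Ak4, Il1rl1 and Arhgap22 did not pass (adjusted p = 0.0904, 0.0888, 0.0770 and 0.0582). Of the Prl2c3 50-base words 60.0% recur in other genes (Prl2c2 the closest), and of those of Ctla2a 25.8%, where fragments that align to several places were not counted. Of the Arhgap22 exon bases 36.9% overlap other genes, most of them Gm15512 on the opposite strand.

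Across 15441 genes tested with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 667 genes were higher and 574 lower in OB at adjusted p under 0.05, 8.0% of those tested. Of the higher genes 419, and of the lower 355, differed by at least 2-fold. DESeq2 gave 1296 higher and 1136 lower, limma-voom 1247 and 1081, and the label-prefix block 1433 and 1256. The libraries of both groups did not overlap for 3937 of the 15441 genes tested. Chance alone gives 5.7% of genes if every grouping of the libraries is equally likely. Among the 1241 called genes 1240 did not overlap, but these were picked on the same libraries, so this is no separate evidence. Without control 2, 190 genes were higher and 107 lower, and without OB 1, 225 and 104. Without OB 2 the counts were 366 and 180, without OB 3 they were 387 and 227, and without OB 4 they were 341 and 202. The calls of 161 higher and 78 lower genes held whichever library was left out. Within label sets, 1030 genes were higher and 560 lower among the C1 and C2 libraries (2 against 2). The libraries with no C number hold 1 control, which was assumed to vary like OB 3 and OB 4. That OB pair was the closest of all pairs of libraries. Counts of calls given below for this label set rest on its spread alone.

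**Figure D1:**
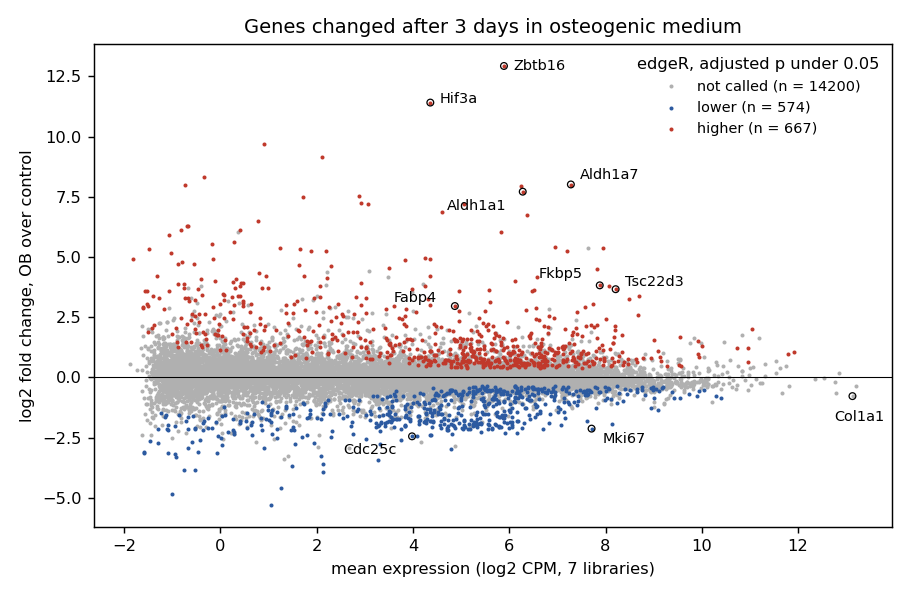
Log2 fold change of OB over control (vertical axis) against mean log2 CPM over the 7 libraries (horizontal axis), 1 point per tested gene, red for the 667 genes higher and blue for the 574 lower at edgeR adjusted p under 0.05, grey for the others. Zbtb16 and Hif3a lie highest among the named genes, at 12.93 and 11.41, and Mki67 lies at -2.13.

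Most glucocorticoid receptor target genes rose. Tsc22d3, which encodes the glucocorticoid-induced leucine zipper protein, rose from 38.7 ± 8.48 CPM (SD, n = 3) to 490 ± 78.3 CPM (SD, n = 4). Fkbp5, a co-chaperone gene of the receptor, rose from 27.8 ± 18.8 to 390 ± 38.2 CPM. The transcription factor genes Cebpd and Klf9 rose from 40.9 ± 4.37 to 268 ± 56.6 CPM and from 35.4 ± 3.34 to 126 ± 26.2 CPM. Of 19 tested members, 14 were higher, 1 was lower and 4 did not pass, and 17 were higher and 1 lower when adjusted over the list alone. The lower member, picked out after its values were seen, was Nr3c1, the gene of the receptor itself (log2 fold change -0.53 ± 0.10, edgeR adjusted p = 0.0200). The log2 fold changes by edgeR of Tsc22d3, Fkbp5, Cebpd and Klf9 were 3.66 ± 0.21, 3.82 ± 0.44, 2.71 ± 0.19 and 1.84 ± 0.17, with adjusted p = 0.000354, 0.00559, 0.000778 and 0.00308. The median over the list was 2.13, and it does not depend on how far Zbtb16 and Lcn2, each with 1 control count, lie above it. The camera test of limma gave the list adjusted p = 1.52e-14 with its preset correlation between genes, and adjusted p = 0.265 with an estimated correlation. Without control 2, 9 members were higher and 0 lower, and the calls of these 9 held whichever library was left out. Nr3c1 was not called without control 2, OB 1, OB 2 or OB 3, each of which left 0 lower members. Tsc22d3 (ENSMUSG00000031431) lies at 140539528 to 140600659 on chromosome X of mm10 and Fkbp5 (ENSMUSG00000024222) at 28399094 to 28517527 on chromosome 17. Cebpd shares 15.0% of its exon bases with other genes, mostly Spidr on the opposite strand.

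Osteoblast lineage genes did not pass as a group. Runx2, the transcription factor gene that commits cells to the bone lineage, stood at 97.1 ± 13.6 CPM (SD, n = 3) in control and 76.6 ± 6.75 CPM (SD, n = 4) in OB. Col1a1, the main collagen gene of bone matrix, stood at 11800 ± 1810 and 6880 ± 1910 CPM, Spp1 (osteopontin) at 444 ± 126 and 310 ± 253 CPM, and Dlx5 at 17.8 ± 2.74 and 15.2 ± 1.46 CPM. Their log2 fold changes were -0.34 ± 0.13, -0.78 ± 0.23, -0.52 ± 0.56 and -0.22 ± 0.16, with edgeR adjusted p = 0.135, 0.0751, 0.610 and 0.410. The other member named from this list, Col1a2, had a log2 fold change of -0.36 (edgeR adjusted p = 0.328). Further markers of the lineage were too rare to test. Alpl (tissue-nonspecific alkaline phosphatase) had 5 counts over the control and 11 over the OB libraries, Sp7 (osterix) 29 and 15, Bglap (osteocalcin) 6 and 6, and Ibsp (bone sialoprotein) 2 and 31. The upper 95% limits of their pooled OB levels, by exact Poisson intervals, were 0.174 CPM for Alpl, 0.219 for Sp7, 0.116 for Bglap and 0.390 for Ibsp. For Ibsp the ratio of pooled CPM was 14.7 (exact binomial interval 3.75 to 127), and DESeq2, which tested it, called it higher (adjusted p = 0.0304). Of the Bglap 50-base words 56.6% recur in other genes, Bglap2 the closest. By edgeR 0 of 18 tested members were higher, 1 was lower and 17 did not pass, with the same counts when adjusted over the list alone. At an unadjusted p under 0.05, 1 was higher and 3 were lower. DESeq2 called 2 higher and 2 lower, and limma-voom called 0 higher and 3 lower. The lower member was Atf4, a transcription factor gene of osteoblasts and of amino acid stress (log2 fold change -0.72 ± 0.17, edgeR adjusted p = 0.0390). The camera test gave the list adjusted p = 0.286, with a median log2 fold change of -0.32. The call of Atf4 ended under the replicate block (adjusted p = 0.0557) and without each library except control 1 (up to 0.116). Col1a1 passed by DESeq2 (adjusted p = 0.0139), by limma-voom (0.0291), with no filter (0.0468), without OB 3 (0.0478) and among C1 and C2 libraries (0.0273), and libraries with no C number gave 4 members higher and 4 lower, C1 and C2 libraries 1 and 1.

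**Figure D2:**
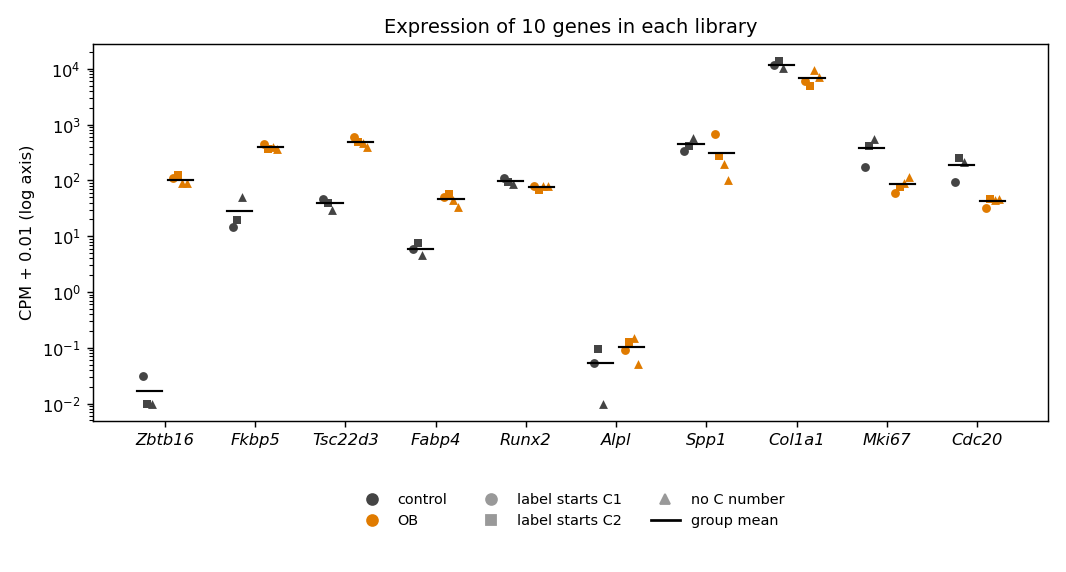
Expression in CPM (log axis, 0.01 added) of 10 genes in each of the 3 control (grey) and 4 OB (orange) libraries, with marker shape for the label set and a line at the group mean. Zbtb16, Fkbp5, Tsc22d3 and Fabp4 lie above all control libraries in every OB library, Mki67 and Cdc20 lie below, and Alpl had 5 and 11 counts in all.

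Among mineralisation and phosphate genes, Mgp, an inhibitor of calcification, rose from 99.9 ± 17.7 CPM (SD, n = 3) to 442 ± 167 CPM (SD, n = 4). Smpd3, a sphingomyelinase gene needed for bone mineralisation, rose from 7.51 ± 1.95 to 33.2 ± 7.68 CPM. Both had a log2 fold change of 2.15 (SE 0.33 and 0.26, edgeR adjusted p = 0.0127 and 0.00613), and both calls held without each library in turn. Of 12 tested members, 2 were higher, 0 were lower and 10 did not pass, over all genes and adjusted over the list alone. At an unadjusted p under 0.05, 2 were lower by edgeR, while DESeq2 and limma-voom called 0 lower. Camera gave the list adjusted p = 0.996 with its direction up and a mean log2 fold change of 0.14, while the median was -0.12. Libraries with no C number gave 4 members higher and 5 lower, and C1 and C2 libraries 2 and 0.

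Many cell cycle genes fell. Cdc20, an activator of the anaphase-promoting complex, fell from 187 ± 82.0 CPM (SD, n = 3) to 41.9 ± 6.87 CPM (SD, n = 4). The mitotic cyclin gene Ccnb2 fell from 97.2 ± 33.9 to 23.0 ± 6.23 CPM, and the kinetochore gene Cenpf from 130 ± 55.6 to 26.4 ± 8.43 CPM. Mki67, the Ki-67 proliferation marker, stood at 170, 405 and 548 CPM in control 1, 2 and 3 and at 60.1 to 115 CPM in the OB libraries. All 35 tested members had negative log2 fold changes, from -2.31 to -0.30 with a median of -1.84. Of these 22 were lower and 13 did not pass, and 33 were lower when adjusted over the list alone. By edgeR the log2 fold changes of Cdc20, Ccnb2 and Cenpf were -2.16 ± 0.31, -2.08 ± 0.29 and -2.31 ± 0.36, with adjusted p = 0.0108, 0.0103 and 0.0127. For Kif20a and Mki67 they were -2.09 ± 0.27 and -2.13 ± 0.38, with edgeR adjusted p = 0.00755 and 0.0187. Camera gave the list adjusted p = 1.09e-15 with its preset correlation, and adjusted p = 0.861 with an estimated correlation. The list score, the mean over members of centred log2 CPM, was -0.09, 1.07 and 1.53 in control 1, 2 and 3 and -0.77 to -0.49 in OB. The number of lower members was 5 without control 2, 4 without OB 1, 8 without OB 2, 12 without OB 3 and 14 without OB 4. It was 6 among the C1 and C2 libraries, 35 among those with no C number, and 33 without control 1. The calls of Cdc20, Ccnb2, Cenpf and Kif20a held whichever library was left out, while that of Mki67 ended without control 2, OB 1 or OB 2 (adjusted p = 0.0615, 0.0637 and 0.0533). Of the Kif20a exon bases 33.2% overlap other genes, mostly Cdc23 on the opposite strand, and Mki67 (ENSMUSG00000031004) lies at 135689784 to 135716361 on chromosome 7 of mm10.

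Some adipocyte genes rose. Fabp4, a fatty acid carrier gene of fat cells, rose from 5.95 ± 1.45 CPM (SD, n = 3) to 46.6 ± 10.5 CPM (SD, n = 4), and the transcription factor gene Klf15 from 0.818 ± 0.588 to 24.3 ± 17.6 CPM. Pparg, which encodes the nuclear receptor that governs fat cell formation, rose from 37.7 ± 1.54 to 54.7 ± 7.96 CPM. Plin4, a lipid droplet coat gene, rose from 69.5 ± 30.1 to 312 ± 164 CPM. By edgeR the log2 fold changes of Fabp4, Klf15, Pparg and Plin4 were 2.96 ± 0.25, 4.87 ± 0.72, 0.54 ± 0.13 and 2.16 ± 0.50, with adjusted p = 0.00188, 0.0110, 0.0454 and 0.0385. Of 16 tested members, 5 were higher, 0 were lower and 11 did not pass, and 5 were higher and 1 lower when adjusted over the list alone. At an unadjusted p under 0.05, 2 were lower, and DESeq2 and limma-voom each called 1 lower. The fifth higher member was Cebpd, which is also in the glucocorticoid list. For the adipocyte list camera gave adjusted p = 0.0244, and adjusted p = 0.981 with an estimated correlation. Control 3 had the lowest list score of the 7 libraries at -1.14, and the list did not pass without it (adjusted p = 0.221) or without OB 2 (0.0983). The calls of Fabp4, Klf15 and Cebpd held whichever library was left out, and 3 members were higher without control 1, 2 or 3 or OB 1 or 2. That of Pparg ended without any 1 of the 7 (adjusted p = 0.0636 to 0.147), with no filter (0.0660) and under the replicate block (0.0512), and that of Plin4 without control 1, 2 or 3, OB 1 or OB 2 (up to 0.103). Libraries with no C number gave 11 members higher and 3 lower, and C1 and C2 libraries and the replicate block each gave 6 and 1.

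Of the chondrocyte genes, Col11a2, a cartilage collagen gene, rose from 12.2 ± 2.70 CPM (SD, n = 3) to 26.4 ± 3.55 CPM (SD, n = 4), and Prg4 (lubricin) from 0.516 ± 0.116 to 4.07 ± 2.58 CPM. By edgeR their log2 fold changes were 1.11 ± 0.19 and 2.99 ± 0.63, with adjusted p = 0.0172 and 0.0297. Sox9, the transcription factor gene of cartilage, stood at 332, 449 and 123 CPM in control 1, 2 and 3 and at 411 ± 154 CPM in OB (edgeR adjusted p = 0.571). Acan (aggrecan) had 0 counts in control and 2 in OB, under the limit of detection. Of 16 tested members, 2 were higher, 0 were lower and 14 did not pass, and 4 were higher and 1 lower when adjusted over the list alone. For the chondrocyte list camera gave adjusted p = 0.0108, and adjusted p = 0.981 with an estimated correlation. Control 3 had a list score of -1.92 against -0.36 to 0.65 in the other libraries, and without it the list gave adjusted p = 0.171. The calls of Col11a2 and Prg4 ended without control 2 (adjusted p = 0.0694 and 0.0959), and that of Prg4 also without control 1 or 3 or OB 1, 2 or 4, and under the replicate block (0.0613). Libraries with no C number gave 13 members higher and 1 lower, C1 and C2 libraries 1 and 0, and the replicate block 1 and 1.

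Pdgfra, a growth factor receptor gene of mesenchymal progenitors, rose from 247 ± 93.8 CPM (SD, n = 3) to 720 ± 81.8 CPM (SD, n = 4), and Nes (nestin) fell from 16.9 ± 9.09 to 4.11 ± 0.447 CPM. By edgeR their log2 fold changes were 1.54 ± 0.27 and -2.04 ± 0.33, with adjusted p = 0.0182 and 0.0143. They were the called members of 18 mesenchymal stromal markers, 1 higher and 1 lower also when adjusted over the list alone. Camera gave that list adjusted p = 0.909 with its direction down and a mean of -0.03, while the median was 0.04. Lmod1, an actin nucleator gene of smooth muscle, rose from 17.5 ± 11.2 to 69.5 ± 20.8 CPM (log2 fold change 1.99 ± 0.50, edgeR adjusted p = 0.0492). It was the called member of 14 smooth muscle contractile genes, of which 2 were higher and 2 lower when adjusted over the list alone (camera adjusted p = 0.815). Acta2 (smooth muscle actin) stood at 960 ± 99.4 and 843 ± 271 CPM and Tpm1 (tropomyosin) at 901 ± 176 and 782 ± 113 CPM, with edgeR adjusted p = 0.678 and 0.484. By edgeR 0 of 5 tested skeletal muscle genes passed, over all genes, adjusted over the list alone or at an unadjusted p under 0.05, as by DESeq2 and limma-voom. Tnni1 stood at 7.49 and 15.0 CPM and Tnnt3 at 1.24 and 0.826 CPM, and camera gave adjusted p = 0.909 with its direction down and a median of -0.43, while the mean was 0.06. The call of Pdgfra ended without control 2 or OB 1 (adjusted p = 0.0545 and 0.0531), that of Nes without OB 1 (0.0508) and that of Lmod1 without each library except control 3 (up to 0.122). Libraries with no C number gave 5 stromal markers lower, 8 smooth muscle genes higher and 2 skeletal muscle genes higher, and C1 and C2 libraries gave 2, 2 and 0. The replicate block gave 1 smooth muscle gene higher and 1 lower, as did leaving out control 3.

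Matrix genes went both ways. Fbln5, an elastic fibre gene, fell from 838 ± 50.8 CPM (SD, n = 3) to 330 ± 88.4 CPM (SD, n = 4), while the glycoprotein genes Tnc and Tnxb rose from 134 ± 16.1 to 310 ± 90.2 CPM and from 1.43 ± 0.830 to 5.43 ± 1.42 CPM. By edgeR the log2 fold changes of Fbln5, Tnc and Tnxb were -1.34 ± 0.20, 1.21 ± 0.24 and 1.91 ± 0.46, with adjusted p = 0.0110, 0.0248 and 0.0442. Of 30 fibrillar collagen and matrix genes, 2 were higher, 1 was lower and 27 did not pass, and 3 were higher and 6 lower when adjusted over the list alone (camera adjusted p = 0.664). Among 25 collagen modification genes, Lox (lysyl oxidase) rose from 2320 ± 345 to 4490 ± 1170 CPM, and Adamts2 (a procollagen N-proteinase) from 141, 142 and 98.6 CPM in control to 183 to 202 CPM in OB. P4ha1, a prolyl hydroxylase gene, fell from 202 ± 85.6 to 82.3 ± 18.3 CPM, and the collagen chaperone gene Serpinh1 from 1290 ± 176 to 886 ± 63.1 CPM. With edgeR the log2 fold changes of Lox, Adamts2, P4ha1 and Serpinh1 were 0.95, 0.62, -1.30 and -0.54, with adjusted p = 0.0435, 0.0421, 0.0320 and 0.0413. The other 21 did not pass, 3 were higher and 2 lower when adjusted over the list alone, and camera gave adjusted p = 0.962. The call of Fbln5 held without each library in turn. That of Lox ended without each library except OB 2 (up to 0.132), by upper-quartile scaling (0.0526) and under the replicate block (adjusted p = 0.0915). The calls of Adamts2 and Tnxb ended without each library except control 3 (up to 0.112 and 0.114), and that of Serpinh1 without each except control 1 (up to 0.129). That of P4ha1 ended without control 2 or OB 1, 3 or 4 (up to 0.0937), and that of Tnc without control 1 or 2 or OB 1 or 4 (up to 0.0871). Among libraries with no C number 14 matrix genes were higher and 4 lower, and 9 collagen modification genes higher and 4 lower. Among C1 and C2 libraries 3 matrix genes were higher and 8 lower, and 1 collagen modification gene higher and 0 lower, while limma-voom called 3 matrix genes higher and 7 lower. Under the replicate block 3 matrix genes were higher and 4 lower, and 1 collagen modification gene higher and 2 lower, while 5 matrix genes were lower without control 3.

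Several amino acid and unfolded protein stress genes fell. Ddit3 (CHOP), a stress transcription factor gene, fell from 71.5 ± 2.34 CPM (SD, n = 3) to 38.5 ± 4.74 CPM (SD, n = 4), and Chac1, whose product degrades glutathione, from 31.8 ± 11.4 to 8.73 ± 2.55 CPM. The alanyl-tRNA synthetase gene Aars fell from 458 ± 72.5 to 233 ± 38.9 CPM, and Herpud1, a gene of endoplasmic reticulum degradation, from 67.5 ± 5.90 to 40.1 ± 5.55 CPM. For edgeR the log2 fold changes of Ddit3, Chac1, Aars and Herpud1 were -0.89 ± 0.12, -1.86 ± 0.31, -0.97 ± 0.17 and -0.75 ± 0.13, with adjusted p = 0.00778, 0.0150, 0.0166 and 0.0175. Of 27 tested members, 7 were lower, 1 was higher and 19 did not pass, and 9 were lower and 1 higher when adjusted over the list alone. The higher member, named after its values were seen, was the chaperone gene Dnajb9 (log2 fold change 0.60 ± 0.11, edgeR adjusted p = 0.0198). For the stress list camera gave adjusted p = 2.22e-05, and adjusted p = 0.861 with an estimated correlation. Control 3 had the highest list score at 0.72, with the others between -0.46 and 0.29. The number of lower members was 1 without control 2, 3 without OB 1 and 4 without OB 2, 3 or 4, and in each of these, as under the replicate block, 0 were higher. It was 21 among libraries with no C number and 7 among C1 and C2 libraries. The call of Ddit3 held without each library in turn, that of Chac1 ended without control 2 (adjusted p = 0.0542), and those of Aars and Herpud1 without control 2 (0.0599 and 0.0624) or OB 1 (0.0548 and 0.0572). Of the Aars exon bases 15.1% overlap other genes, mostly Exosc6, and of those of Ddit3 10.9% overlap a further entry of the same name.

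Most nuclear genes of oxidative phosphorylation had small negative log2 fold changes. Atp5a1, which encodes a subunit of ATP synthase, fell from 688 ± 34.9 CPM (SD, n = 3) to 514 ± 20.7 CPM (SD, n = 4), and Atp5b stood at 1620 ± 276 and 1150 ± 51.9 CPM. By edgeR their log2 fold changes were -0.42 ± 0.10 and -0.49 ± 0.13, with adjusted p = 0.0381 and 0.0589. Of 26 tested members 25 had negative log2 fold changes, with a median of -0.21. Only Atp5a1 of the 26 was called over all genes, and 0 when adjusted over the list alone. Camera gave the list adjusted p = 0.000499, and adjusted p = 0.827 with an estimated correlation. The call of Atp5a1 ended without any 1 of the 7 libraries (adjusted p = 0.0511 to 0.127), with no filter (0.0798) and under the replicate block (0.0776). DESeq2 called 3 members lower and limma-voom 6, Atp5b among them (adjusted p = 0.0147 and 0.0325), and libraries with no C number gave 14, C1 and C2 libraries 0. The share of counts on mitochondrial genes, in contrast, was 1.55% to 1.61% in the control and 1.70% to 1.97% in the OB libraries.

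Cholesterol synthesis genes passed as a list by camera but not singly. Srebf2, which encodes the transcription factor that governs the pathway, stood at 530 ± 92.9 CPM (SD, n = 3) in control and 368 ± 39.0 CPM (SD, n = 4) in OB, and Hmgcs1 at 337 ± 15.8 and 260 ± 84.5 CPM. By edgeR their log2 fold changes were -0.53 and -0.38, with adjusted p = 0.0693 and 0.369. By edgeR 0 of 25 passed over all genes or adjusted over the list alone, and 2 were lower and 0 higher at an unadjusted p under 0.05. The median was -0.18, with 21 negative values. Camera gave the list adjusted p = 0.0359, adjusted p = 0.981 with an estimated correlation and adjusted p = 0.408 under the replicate block. The list did not pass without control 1 (adjusted p = 0.0693), control 3 (0.158), OB 2 (0.209) or OB 4 (0.418). DESeq2 and limma-voom each called 1 member lower and 0 higher, Srebf2 passed by both (adjusted p = 0.0239 and 0.0115) and without control 3 (0.0298), and libraries with no C number gave 7 members lower, C1 and C2 libraries 1.

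Among hypoxia and glycolysis genes, Adm (adrenomedullin) rose from 10.1 ± 2.35 CPM (SD, n = 3) to 39.3 ± 8.24 CPM (SD, n = 4; log2 fold change 1.97 ± 0.23, edgeR adjusted p = 0.00559). P4ha1 was the lower member, and Vegfa, an angiogenic growth factor gene, stood at 80.2 ± 30.1 and 63.7 ± 4.24 CPM (edgeR adjusted p = 0.382). Of 27 tested members 25 did not pass, and 1 was higher and 3 lower when adjusted over the list alone. At an unadjusted p under 0.05, 2 were higher and 10 lower, DESeq2 called 1 higher and 7 lower, limma-voom 2 and 3, and the label-prefix block gave 2 and 7. Camera gave the hypoxia list adjusted p = 0.122, with a median of -0.57. Control 3 had a hypoxia list score of 0.75 against -0.22 to 0.04 in the others, and the list passed without control 1 (adjusted p = 0.0402) or control 2 (0.00742). By edgeR 0 of 18 NRF2 target genes, which serve the antioxidant response, passed over all genes, and 2 were higher and 0 lower when adjusted over the list alone. At an unadjusted p under 0.05, 3 were higher and 7 lower, and DESeq2 and limma-voom each called 2 higher and 1 lower (camera adjusted p = 0.201). Txnrd1 (thioredoxin reductase) stood at 281 ± 160 and 179 ± 17.2 CPM and Tkt (transketolase) at 252 ± 66.0 and 186 ± 37.0 CPM. Libraries with no C number gave 3 hypoxia genes higher and 20 lower, and 3 NRF2 targets higher and 10 lower. C1 and C2 libraries gave 2 hypoxia genes higher and 4 lower, and 4 NRF2 targets higher and 0 lower. Under the replicate block 2 hypoxia genes were higher and 3 lower, as without control 3, and 3 NRF2 targets were higher and 0 lower. Without control 1, 3 NRF2 targets were lower, and without control 3, 1 was higher and 1 lower.

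Immune gene lists held few calls. Ifih1, a sensor gene of viral RNA, rose from 2.31 ± 0.987 CPM (SD, n = 3) to 7.37 ± 2.43 CPM (SD, n = 4; log2 fold change 1.66 ± 0.38, edgeR adjusted p = 0.0387). It was the called member of 23 interferon response genes, of which 4 were higher and 1 lower when adjusted over the list alone. Stat2 stood at 94.4 ± 26.7 and 132 ± 21.7 CPM and Ddx58 at 83.0 ± 26.7 and 92.3 ± 27.0 CPM. Camera gave the interferon list adjusted p = 0.0235, adjusted p = 0.981 with an estimated correlation and adjusted p = 0.129 under the replicate block. Control 3 had an interferon list score of -1.68 against -0.38 to 1.14 in the others, and the list did not pass without it (adjusted p = 0.549) or without OB 3 (0.109). Of 16 genes of inflammatory cytokines and NF-κB targets, Lcn2, which encodes an iron-scavenging secreted protein, rose from 1 count to 1099 counts (ratio of pooled CPM 1040, exact binomial interval 187 to 41300). Of these counts 906 came from OB 2, so the pooled ratio rests mainly on that library. Nfkbia, the NF-κB inhibitor gene, rose from 36.8 ± 5.04 to 90.2 ± 20.2 CPM (log2 fold change 1.29 ± 0.19, edgeR adjusted p = 0.0120). Both Lcn2 and Nfkbia are also in the glucocorticoid list. The other 14 did not pass, 4 were higher and 2 lower when adjusted over the list alone, and camera gave adjusted p = 0.625. The calls of Ifih1, Lcn2 and Nfkbia ended without control 2 (adjusted p = 0.123, 0.101 and 0.0505). Those of Ifih1 and Lcn2 also ended without control 3 or OB 1, that of Lcn2 without control 1, and that of Ifih1 without OB 2, 3 or 4 and under the replicate block (adjusted p = 0.0915). Libraries with no C number gave 21 interferon genes higher and 1 lower, and 5 inflammatory genes higher and 7 lower. C1 and C2 libraries gave 2 interferon genes higher and 3 lower, with a median of -0.21, and 6 inflammatory genes higher and 0 lower. Under the replicate block 1 interferon gene was higher and 1 lower, and 4 inflammatory genes were higher and 0 lower.

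Signalling lists gave no call as groups by camera or by the direction test of fry. The mixed test of fry lets members move either way. It gave adjusted p = 0.000603 for BMP and TGF-beta targets, 0.172 for Wnt, 0.172 for Notch and 0.199 for immediate early genes. Grem1, a gene of a secreted antagonist of bone morphogenetic proteins, fell from 331 ± 145 CPM (SD, n = 3) to 53.9 to 129 CPM in OB (n = 4; log2 fold change -1.82 ± 0.35, edgeR adjusted p = 0.0228). Of 21 BMP and TGF-beta targets 1 was higher, 1 was lower and 19 did not pass, 1 was higher and 2 lower when adjusted over the list alone, and camera gave adjusted p = 0.664. Dkk2, a Wnt modulator gene, rose from 4.14 ± 1.27 to 10.0 ± 3.11 CPM (log2 fold change 1.27 ± 0.30, edgeR adjusted p = 0.0432). It was the called member of 24 Wnt genes, with 0 adjusted over the list alone (camera adjusted p = 0.753). Rspo2 stood at 602 ± 233 and 321 ± 58.4 CPM and Fzd1 at 375 ± 137 and 218 ± 30.1 CPM (edgeR adjusted p = 0.0907 and 0.103), and both passed without control 3 (0.0123 and 0.00932), by DESeq2 (0.0217 and 0.0357) and by limma-voom (0.00998 and 0.00700). By edgeR 0 of 12 Notch genes passed over all genes or adjusted over the list alone, and 1 was higher and 1 lower at an unadjusted p under 0.05. DESeq2 called 1 Notch gene lower and limma-voom 2, and camera gave adjusted p = 0.909 with its direction up and a median of 0.09, while the mean was -0.03. Notch3 stood at 148 ± 72.9 and 218 ± 34.3 CPM and Notch1 at 107 ± 63.6 and 160 ± 59.5 CPM. Dusp1, a phosphatase gene of the immediate early class, rose from 14.1 ± 6.05 to 40.6 ± 15.4 CPM (log2 fold change 1.53 ± 0.37, edgeR adjusted p = 0.0459). Dusp1, which is also in the glucocorticoid list, was the called member of 22 immediate early genes, with 0 adjusted over the list alone (camera adjusted p = 0.831). Egr1 stood at 111 ± 91.2 and 133 ± 127 CPM and Ccn1 at 128 ± 84.4 and 167 ± 108 CPM. The call of Grem1 ended without OB 1 or OB 3 (adjusted p = 0.0765 and 0.0574). That of Dkk2 ended without each library except control 1 (up to 0.138), and that of Dusp1 without each except control 3 (up to 0.143) and under the replicate block (adjusted p = 0.0655), where Rspo2 passed (0.0470). Among C1 and C2 libraries 11 immediate early genes were higher and 0 lower, and among libraries with no C number 3 were higher and 16 lower. The latter also gave 6 BMP and TGF-beta targets higher and 8 lower, 7 Wnt genes higher and 5 lower, and 4 Notch genes higher and 2 lower, and the former gave 5 and 2, 1 and 2, and 0 and 0 in the same order. Under the replicate block 5 Wnt genes were higher and 1 lower, 2 BMP and TGF-beta targets higher and 2 lower, and 0 immediate early genes higher, while 2 immediate early genes were higher without control 3.

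Markers of other cell types were rare and did not pass. Of 12 macrophage markers 5 could be tested, led by Cd14 at 8.35 ± 2.60 CPM (SD, n = 3) in control and 7.93 ± 2.25 CPM (SD, n = 4) in OB and Cd68 at 2.36 ± 0.445 and 2.33 ± 0.438 CPM (edgeR adjusted p = 0.909 and 0.963). Camera gave the macrophage list adjusted p = 0.962 with its direction up and a mean of 0.02, while the median was -0.07. Of 11 endothelial and 12 epithelial markers 2 each were tested, too few for a test of the list. Tek stood at 5.59 and 5.66 CPM and Egfl7 at 2.62 and 1.69 CPM, and Cdh1 (E-cadherin) at 1.87 and 0.882 CPM and Krt19 (a keratin) at 0.573 and 0.573 CPM. In all 3 lists 0 members passed by edgeR over all genes, adjusted over the list alone or at an unadjusted p under 0.05, and 0 by DESeq2 or limma-voom.

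**Figure D3:**
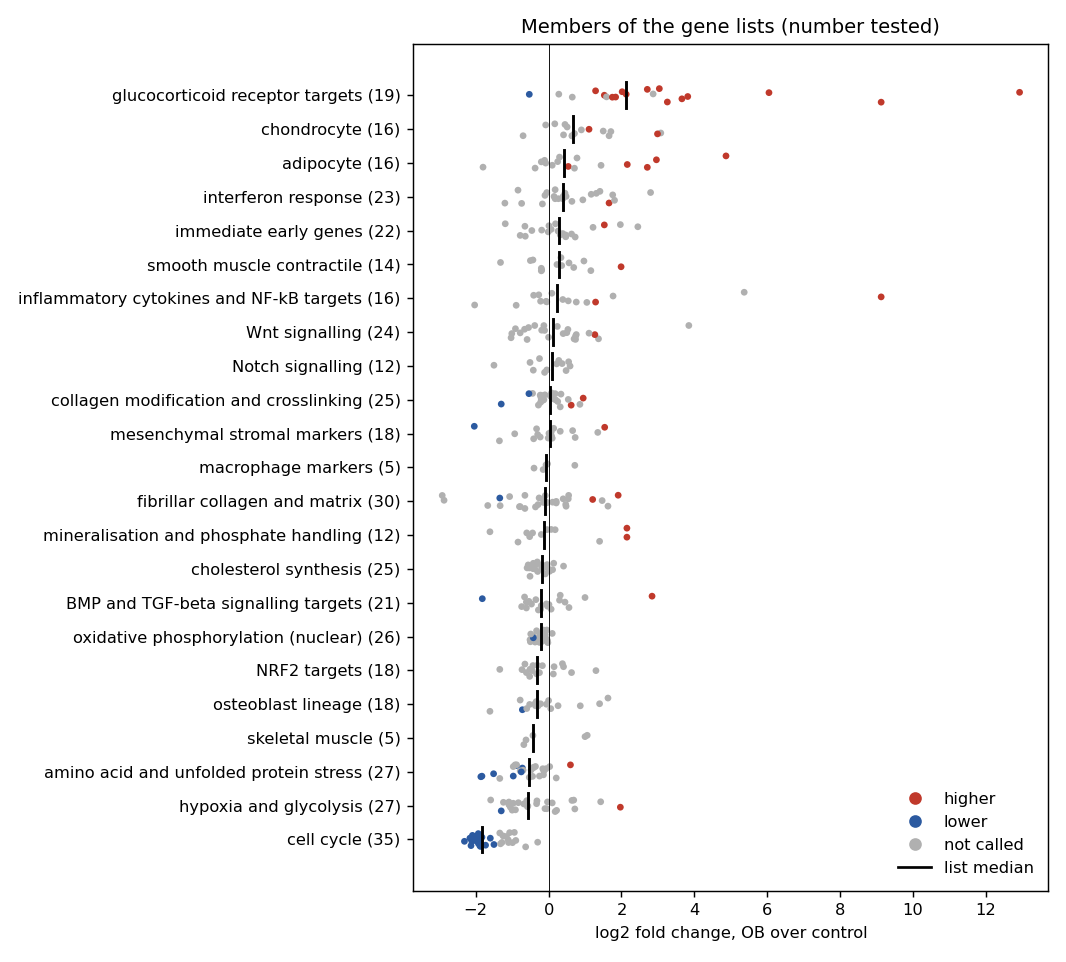
Log2 fold change of OB over control for the tested members of the 23 gene lists with at least 5 tested genes, red for members higher and blue for members lower at edgeR adjusted p under 0.05, grey for the rest, with a black bar at the list median. Glucocorticoid receptor targets have a median of 2.13 and cell cycle genes of -1.84, and the other medians lie between -0.57 and 0.68.

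Of 25 lists fixed before the data were examined, 23 could be tested. Camera called 4 higher (glucocorticoid receptor targets, chondrocyte, interferon response and adipocyte) and 4 lower (cell cycle, amino acid and unfolded protein stress, oxidative phosphorylation and cholesterol synthesis). With an estimated correlation it called 0 and 0. The estimated correlations of these lists were 0.11 to 0.82, against the preset 0.01. The rotation test fry of limma, in the form that asks only whether a list moves on balance in 1 direction, called 2 lists. These were glucocorticoid receptor targets upwards (adjusted p = 0.000317) and oxidative phosphorylation downwards (adjusted p = 0.0456). In the mixed form of fry most lists passed. Those that did not were osteoblast lineage, skeletal muscle, interferon, Wnt, Notch, cholesterol synthesis, immediate early genes and macrophage markers. Their adjusted p by mixed fry was 0.0698 to 0.846.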

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

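The tests of the label sets, of sequencing depth, of the cell cycle list and of the osteoblast list were chosen only after the result was seen, while the splits of the libraries and the length trend were planned. The cell cycle tests were changed again after their values were seen, and ended as the number of members still called. They began as score differences of 1.12 and 1.19, held against 2 SD of the OB libraries and then of the more variable group. The second bound, from a control SD of 0.83, was not reached. In groups of 4, a library was set apart where its gap to the nearest other relative to the range (Dixon's ratio) passed the critical value at 5%, which 7 of 126 OB values did (5.6%, where chance gives 5%). Runx2 in OB 2 stood at 66.5 CPM against 79.6 to 80.6 in the other OB libraries (ratio 0.925). Acan was seen in OB 4 alone, at 0.0827 CPM against 0, where a ratio of 1 is fixed by the zeros and rests on 2 counts. Dkk2 stood at 14.7 CPM in OB 1 against 8.36 to 8.67 (ratio 0.951), and Fzd1 at 263 CPM in OB 1 against 199 to 205 (ratio 0.903). The total count of OB 2 was 43403730 against 21213328 to 24816216 in the other OB libraries (ratio 0.838). The NRF2 list score of OB 4 was -0.201 against -0.0311 to -0.000853 (ratio 0.849). The ratio of the seventh value was 0.897.

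Whether chance alone could give so many changed genes was tested by refitting all 35 splits of the 7 libraries into 3 and 4. Only 1 split, the real one with 1241 genes, gave as many, and the highest other gave 65. That other split set control 3, OB 3 and OB 4 against the rest, as the label sets do. Of the 8 splits that part 3 pairs of replicate numbers, the highest other gave 0 genes. A share of 1 in 35, or 1 in 8 with the pairs kept, is the smallest that these splits can reach. The offset shared by label sets, described below, also means that the libraries are not freely exchangeable. The 35 splits therefore argue against chance without excluding it, and the 8 splits are too few to decide.

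The label sets shared an offset. Across 15441 genes, which are not independent replicates, the difference of C1 and C2 from no C number in control correlated with that in OB at r = 0.41 (SD 0.015 over random subsets of genes), and these differences share no library. Depth is argued against, because OB 1, with a total close to those of OB 3 and OB 4, gave r = 0.34, and so is a trend with gene length, whose removal left r = 0.41. A difference between the sets that acts on both groups alike, for which no batch record was available here, may account for the offset, and it could be technical or biological.

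The cell cycle list was lower in OB by a score of 1.46, with an SD of 0.11 among OB and 0.83 among control libraries, and each control score lay above each OB score. No single control library accounted for every call, since 33, 5 and 16 members were still called lower without control 1, 2 and 3. The size of the fall depended on the controls. Nor did the label sets account for every call, since 22 members were still lower in the fit with the label-prefix block. The median log2 fold change was -1.81 with that block and -1.84 without it. Because the bound on these counts was chosen after they were seen, no further conclusion is drawn from them. Culture density or time since plating, which the labels do not give, may differ between untreated and induced cultures and could not be told apart from the treatment. A fall of proliferation under induction therefore remains a hypothesis.

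Osteoblast genes were not higher as a list. Too few reads for Sp7, Alpl and Ibsp is argued against as a reason to have missed a level of 1 CPM. The highest upper limit of their pooled OB levels was 0.39 CPM. For Bglap the limit cannot decide, because 56.6% of its 50-base words recur in other genes and fragments that align to several places were not counted. By edgeR the filter on low counts is argued against too, because 0 further members were called higher without it. DESeq2, which tested Ibsp, called it higher (adjusted p = 0.0304). Ibsp still had a ratio of 14.7 (exact binomial interval 3.75 to 127) at a level of 0.275 CPM, so a rise at very low levels may be present. An early time point, at 3 days, stays open as a biological explanation that was not tested.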

How the results depend on the processing

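Counts of called list members under each setting, and counts of calls that held under every omission, were chosen only after the data were seen, and the other settings were planned. Both scaling alternatives, no filter and the replicate block kept the main counts within 1.5 times. The replicate block gave 831 genes higher and 522 lower, of which 510 and 377 were shared with the unpaired fit, and it changed no call of a named gene or list other than those given in the report. No gene called in the report changed sign in any setting, while 55 uncalled values of named genes and lists changed sign and stayed uncalled. For genes higher in OB by at least 2-fold and genes lower in OB by at least 2-fold, counts follow in brackets. DESeq2 gave 1296 higher and 1136 lower (712 and 567), with more false calls in the data simulated from edgeR dispersions, and limma-voom 1247 and 1081. The label-prefix block gave 1433 and 1256 (715 higher). A threshold of 0.01 left 108 and 36 (96 and 27), and glmTreat against 1.5-fold left 165 and 72, all of them over 2-fold. C1 and C2 libraries alone gave 1030 higher, and no C number alone 3052 and 3413 (1607 and 1038), where Ccn1 and Egr1 turned negative (log2 fold changes -1.56 and -3.09). Leaving out each library gave 190 to 575 higher and 104 to 703 lower (165 to 349 and 81 to 476). A stricter threshold gives fewer calls by construction. The number of libraries alone did not set the counts. Without control 1, 480 genes were higher and 703 lower, and without control 2, 190 and 107. The cause of these differences was not tested.

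With an estimated correlation 0 lists were higher and 0 lower, with fry 1 and 1, and without control 3, 1 was higher. With the estimated correlation adjusted p was 0.981 for adipocyte, chondrocyte, interferon and cholesterol, 0.861 for cell cycle and stress, 0.827 for oxidative phosphorylation and 0.265 for glucocorticoid targets. The estimated correlations were 0.82 for cell cycle, 0.80 for interferon, 0.75 for cholesterol, 0.48 for adipocyte and 0.42 for stress. They were 0.41 for chondrocyte, 0.22 for glucocorticoid targets and 0.11 for oxidative phosphorylation, against the preset 0.01. A correlation above the preset raises camera p-values by construction. By fry it was 0.167 for adipocyte and stress, 0.303 for chondrocyte, 0.116 for cell cycle, 0.672 for interferon and 0.684 for cholesterol. The replicate block and the label-prefix block gave 0.129 and 0.0737 for interferon and 0.408 and 0.0973 for cholesterol. Leaving out each library gave 0.00272 to 0.221 for adipocyte, 0.00012 to 0.171 for chondrocyte, 0.00017 to 0.549 for interferon, 6.65e-05 to 0.418 for cholesterol and 0.00742 to 0.643 for hypoxia (camera adjusted p). The cause of the other shifts was not tested. Of 60 called named genes, 28 lost their call without control 2, 29 without OB 1, 19 each without OB 2 and without OB 4, 18 without OB 3, 12 without control 1 and 11 without control 3. Lost calls numbered 4 with limma-voom, 0 with DESeq2, 11 under the replicate block and 1 under the label-prefix block. They numbered 2 with no filter, 1 with upper-quartile scaling, 11 among C1 and C2 libraries, 41 at a threshold of 0.01 and 32 by glmTreat. Alpl, Sp7, Bglap, Ibsp and Acan, which the filter leaves untested, did not pass without it (adjusted p = 0.587, 0.587, 1, 0.0677 and 0.553).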

Other observations

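The lists in this part and their tests were chosen only after the data were seen, so that their counts describe these libraries and are no independent evidence. Several acute phase and plasma protein genes rose. Hp (haptoglobin) rose from 4.89 ± 3.82 CPM (SD, n = 3) to 212 ± 117 CPM (SD, n = 4), Lbp, which binds bacterial lipopolysaccharide, from 7.28 ± 5.36 to 117 ± 45.3 CPM, and Cp (ceruloplasmin) from 27.1 ± 13.8 to 145 ± 61.0 CPM. Of 15 tested members 7 were higher, with edgeR adjusted p = 0.0151, 0.0188 and 0.0221 for these 3, 0 were lower and 8 did not pass. Of 21 xenobiotic metabolism genes 7 were higher, 0 were lower and 14 did not pass, the higher ones including Sult1a1, a sulfotransferase gene (log2 fold change 6.05 ± 0.74, edgeR adjusted p = 0.00660), and Ephx2, an epoxide hydrolase gene (3.77 ± 0.47, 0.00707). Sult1a1 is also in the glucocorticoid list, as is Lcn2, which was among the higher acute phase genes. Control 3 stood below control 1 and 2 on both lists, with scores of -3.30 against -1.37 and -0.92 for acute phase genes and -2.12 against -0.52 and -0.62 for xenobiotic genes. Several of these genes differed between label sets in OB. Hp stood at 313 CPM in OB of C1 and C2 and 111 CPM in OB without a C number, Apoe at 133 and 23.8 CPM, and Fmo1 at 237 and 85.4 CPM.

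Some circadian clock genes rose and others fell. Per1, a clock repressor gene, rose from 52.0 ± 12.8 CPM (SD, n = 3) to 212 ± 29.3 CPM (SD, n = 4), and Nfil3 from 20.1 ± 6.42 to 57.1 ± 16.1 CPM. Dbp, a clock output gene, fell from 38.3 ± 21.6 to 7.37 ± 1.22 CPM, and Per3 from 91.1 ± 35.7 to 34.9 ± 7.54 CPM. By edgeR the log2 fold changes of Per1, Nfil3, Dbp and Per3 were 2.02, 1.51, -2.38 and -1.39, with adjusted p = 0.00379, 0.0226, 0.0173 and 0.0297. Of 16 tested members 2 were higher, 5 were lower and 9 did not pass. Per1 is also in the glucocorticoid list. Of 11 retinoid genes Aldh1a1 and Aldh1a7 were higher and Rdh10, a retinol dehydrogenase gene, was lower (log2 fold change -2.07, edgeR adjusted p = 0.00408), and 8 did not pass.

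A hypothesis was that the fall was larger for mitotic than for replication members of the cell cycle list. Of 21 mitotic members 21 were lower, and of 14 replication members 1 was (Mcm5, log2 fold change -1.83). These counts depend on the threshold over all genes, since 33 of the 35 members were lower when adjusted over the list alone. The median log2 fold changes were -1.95 for mitotic and -1.1 for replication members. The replication score of control 1 (-0.37) lay below those of OB 1 and OB 2 (-0.24 and -0.26). The mitotic minus the replication score was 0.46, 0.88 and 0.22 in control 1, 2 and 3 and -0.89, -0.60, -0.12 and 0.04 in OB 1, 2, 3 and 4, so that each control lay above each OB library. Of the 35 splits of the libraries 2 gave a difference as large as the real one of 0.91 in either direction (exact permutation p = 0.0571), the real split and 1 of opposite sign. The test was kept in both directions because the direction was taken from the same libraries, and its bound was loosened after the 2 splits were seen. The hypothesis stays open.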
